A study of Mus musculus with 6 samples.

How the data were processed

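RNA of 2 mouse melanoma cell lines, B16-F1 and D5.1G4, was measured on 6 one-colour Agilent mouse 4x44K v2 microarrays, 3 for each line. Per the labels, cells of both lines were untreated and grown for 24 h in RPMI-1640 medium with 10% fetal bovine serum, 1000000 cells to a well of a 6-well plate, to a confluence between 75% and 95%, and the extracted RNA was treated with DNase. The group and the replicate number of each array were taken from its title. The labels do not say whether the 3 replicates of a line were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

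The deposited scanner output gives each spot's intensity on a linear scale, produced with Agilent Feature Extraction 11.0.1.1 from a Cy3 scan, per the file headers. The processed intensity used here had its background subtracted and spatial and multiplicative trends removed within the array, and low values replaced by a surrogate derived from the spot's error, per the file headers. No step between arrays had been applied to it. The deposited files also mark with a 0 or 1 whether a spot is well above background, saturated, non-uniform or an outlier among its replicate spots, per the file headers. The authors' own processed table holds values on a log2 scale for 22147 probes. Each of its columns correlated with the log2 signal of its own array at r = 0.999 or more across probes, above the highest value with another array, 0.993. The column medians lay at 9.71 and the maxima at 18.0, and all 22132 probes that were well above background on at least 3 arrays are in it. How the authors normalized it is not given in the sources used here. The 75th percentiles of its columns agreed too, at 12.25, as quantile normalization would make them. The authors' values and quantile normalization may therefore not be separate alternatives. All per-sample columns were mapped to a sample. The array's annotation is on the mm9 build.

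Each array held 43020 spots other than controls, for 39429 probes, of which 399 had more than 1 spot. The log2 of the processed intensity was taken and the 75th percentile of the array subtracted. Spots marked non-uniform or as outliers, 0.67% to 1.58% of an array, were set to missing, and spots of a probe were averaged. No spot was saturated. The files give accessions, which were matched without their version to the RefSeq gene table of the GRCm38.p6 assembly. This table was used for names, chromosomes and gene order, and none of its coordinates is given because its assembly differs from the array's. Of the probes, 27234 (69.1%) matched 1 gene, 0 matched several and 12195 matched none and remained features of their own. Of the 20659 genes with a probe, 5476 had more than 1, and the probe with the highest mean over all 6 arrays stood for the gene. A feature was tested if its probe was well above background on at least 3 of the 6 arrays.

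The 2 lines were compared with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, with the line as the only term and Benjamini-Hochberg adjustment over all features tested. Differences are B16-F1 minus D5.1G4, since the series text takes D5.1G4 as the reference. A feature was called at an adjusted p of 0.05 or less and a fold of at least 2, the sizes the series text sets without naming a test, normalization or adjustment. Adjusted p-values of genes are from this limma test, 2-sided, with n = 3 arrays in each line unless another number is given. A gene with no probe well above background on any array of a line has only a bound there. The fold is then given as "at least", from the brighter line's mean over its replicates against the dimmer line's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The number of arrays limits the precision of all values.

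The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 12 called genes with the largest positive and the 12 with the largest negative difference that were well above background on all arrays of the brighter line and whose arrays did not overlap between the lines, leaving out clone, predicted and accession names. It adds up to 4 called members with the largest difference from each gene list, and Foxc2, Tgfb1, Vegfa, Ccl2, Cdkn2a, Actb and Gapdh whatever their values. Other list members are named to complete a count or as examples, chosen after their values were seen. The values of 1 gene that the rule took are not reported here. The 32 gene lists, on melanocyte identity, immune recognition, matrix and adhesion, growth and signalling, metabolism and stress, and markers of other cell types, were also fixed before. Each list with at least 5 tested members was tested with camera at a preset inter-gene correlation of 0.01, 2-sided, with adjustment over the 31 lists tested. A missing value was replaced by the mean of its line for the list tests. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, were run beside it.

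The test was tried on simulated values for the same 18442 features with known changes. Of 50 features changed 1.5-fold, which lies under the minimum fold, 0 were called. The test called 31 of 50 changed 3-fold, 40 of 50 changed 6-fold and 42 of 50 changed 12-fold. Of 18242 unchanged features, 3 were called. The simulated noise was normal, independent between features and without an effect of slide. These counts therefore do not give the error rate in the real arrays.

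Array slides were taken from the scan session in the file headers, an assignment that could not be checked against slide barcodes. Slide 1 held B16-F1 replicates 2 and 3, slide 2 held B16-F1 replicate 1 and D5.1G4 replicates 2 and 3, and slide 3 held D5.1G4 replicate 1. Only slide 2 holds both lines, so a fit with slide as a block takes the difference from slide 2 alone. Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the authors' values, no filter or a stricter filter on dim probes, other ways to combine probes, outlier spots kept, saturated features left out, trend and robust variance, array weights, other thresholds, the replicate number as a block, slide as a block, and leaving out each array. Normexp was planned on the mean spot signal, but was run on the median spot and background signals, the columns used here. Slide as a random block, the arrays of slide 2 alone, the arrays of slide 1 left out and the upper part of the features by mean signal were added after seeing the data. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.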

Results

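The data describe 2 mouse melanoma lines grown in culture without treatment: B16-F1, a line of the widely used B16 melanoma of the C57BL/6 mouse, and D5.1G4. The series title places the comparison among murine melanomas that differ in tumorigenicity, and the comparison asks which transcripts differ between the lines. Each line was measured on 3 one-colour microarrays. Between 53.4% and 62.0% of the spots of an array were well above background, with 54.4%, 62.0% and 61.7% on B16-F1 replicates 1, 2 and 3 and 53.9%, 53.4% and 53.5% on D5.1G4 replicates 1, 2 and 3. The 75th percentile of the signal ran from 838.9 to 2034.6, and these levels were equalised before the comparison. Correlations across features were 0.983 to 0.990 between B16-F1 arrays, 0.986 to 0.993 between D5.1G4 arrays and 0.942 to 0.957 between the lines, where features are not independent replicates. The median SD of a feature over the 3 arrays of a line was 0.17 log2 units in B16-F1 and 0.20 in D5.1G4.

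B16-F1 and D5.1G4 differed widely. Of 18442 features tested, 2799 (15.2%) were called, 1159 higher and 1640 lower in B16-F1, and 2093 of these had a gene name (954 higher, 1139 lower). The median fold of the called features was 2.85. The arrays of the lines did not overlap in 2725 of the called features, and in 50.7% of all features measured on every array, where chance gives 10%. In 466 called features (281 higher, 185 lower) the gene was not well above background on any array of the dimmer line. This split may depend on the slide, since the 2 arrays of slide 1, both B16-F1, had the most spots well above background (62.0% and 61.7%). That was not tested. Adjusted p alone, with no minimum fold, took 6434 features. With slide as a block 2587 features were called (988 higher, 1599 lower), of which 2201 were shared with the same direction, and the 3 arrays of slide 2 alone, 1 B16-F1 array against 2 D5.1G4 arrays whose spread stands for both lines, gave 2739. Without the 2 arrays of slide 1, which leaves 1 B16-F1 array whose spread is taken from D5.1G4, 2134 were called, 1901 of them shared. Normexp background correction lowered the count to 1274 (553 higher, 721 lower).

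**Figure D1:**
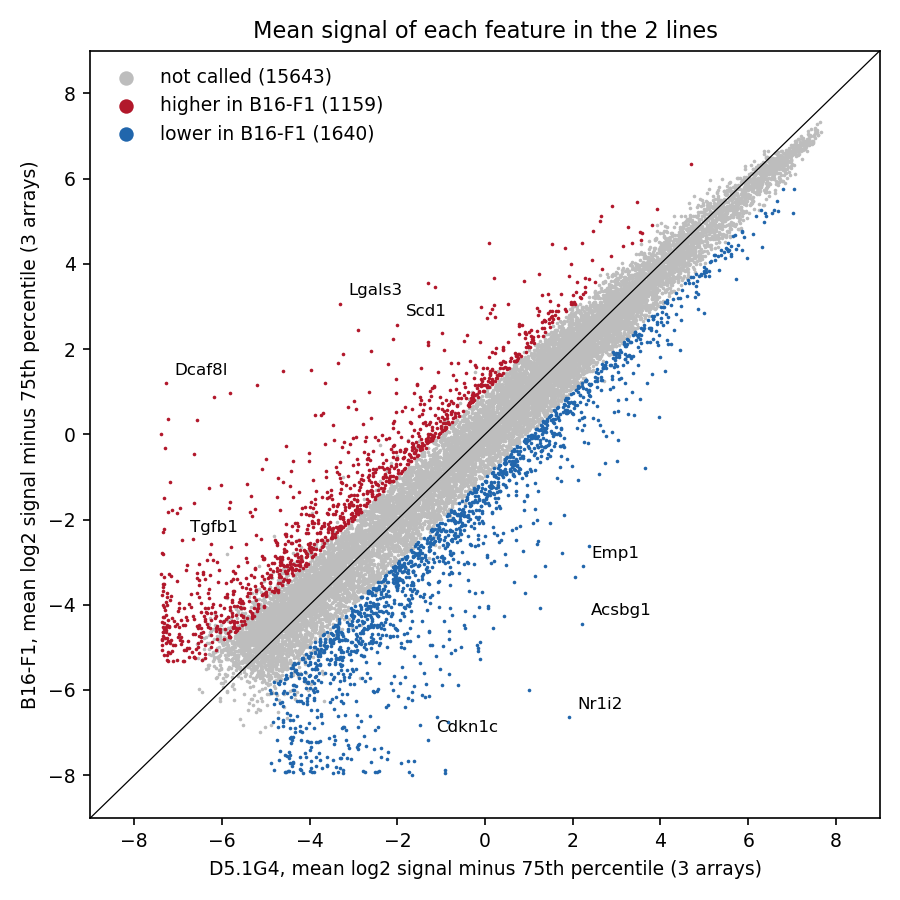
Mean log2 signal minus the array's 75th percentile of each of the 18442 features in B16-F1 (vertical axis) against D5.1G4 (horizontal axis), each a mean of 3 arrays, with the line of equal signal in black. The 1159 red points are called higher and the 1640 blue points called lower in B16-F1, and the points along the lower edges are features close to background in 1 of the lines.

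Of the 12 genes with the largest positive fitted differences, 10 were not well above background on any D5.1G4 array. Lgals3, which encodes galectin-3, a carbohydrate-binding protein, was 83.1-fold higher in B16-F1 (log2 difference 6.38, SE 0.15, adjusted p = 1.29e-05), and Qpct, an enzyme that forms pyroglutamate at the ends of peptides, was 68.8-fold higher (adjusted p = 1.25e-05). Both were above background on every array. Of the other 10, Dcaf8l was at least 80.7-fold higher, Cyba, a subunit of the superoxide-producing NADPH oxidase, at least 75.0-fold, the tight junction protein gene F11r at least 68.6-fold and Mtus2 at least 64.0-fold, where another Mtus2 probe gave a log2 difference of 3.46. Bounds for Rnf113a2 (at least 44.7-fold), Tor4a, Mfsd13a, Anpep (aminopeptidase N), Ldhd and Gpm6b were lower, down to 12.5-fold for Gpm6b. The largest of the adjusted p-values of these 12 genes was that of Mtus2, 0.000166.

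Among the genes lower in B16-F1, Nr1i2, the pregnane X receptor, a nuclear receptor for foreign compounds, was at least 191-fold lower (adjusted p = 0.00011) and was not well above background on any B16-F1 array. Acsbg1, a fatty acid activating enzyme, was 101-fold lower (log2 difference -6.66, SE 0.38, adjusted p = 0.00013) and remained above background in both lines, as did the RNA-binding protein gene Bicc1 (42.1-fold), the membrane protein gene Emp1 (40.3-fold) and the vomeronasal receptor gene Vmn1r132 (40.2-fold). Cdkn1c, a cyclin-dependent kinase inhibitor, was at least 20.3-fold lower. Padi4, which converts arginine in proteins to citrulline, was at least 26.6-fold lower, and the receptor gene Vmn1r148 at least 28.1-fold. Enpep, Gucy1a1, Samd5 and Nacad were lower by at least 15.2-fold, 14.9-fold, 18.1-fold and 8.83-fold. Each gene taken by the naming rule and measured on all 6 arrays had its 3 B16-F1 values all above or all below its 3 D5.1G4 values. The rule itself required this of the genes with the largest differences, and 2725 of the 2799 called features did not overlap. It is therefore no separate support for these genes.

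**Figure D2:**
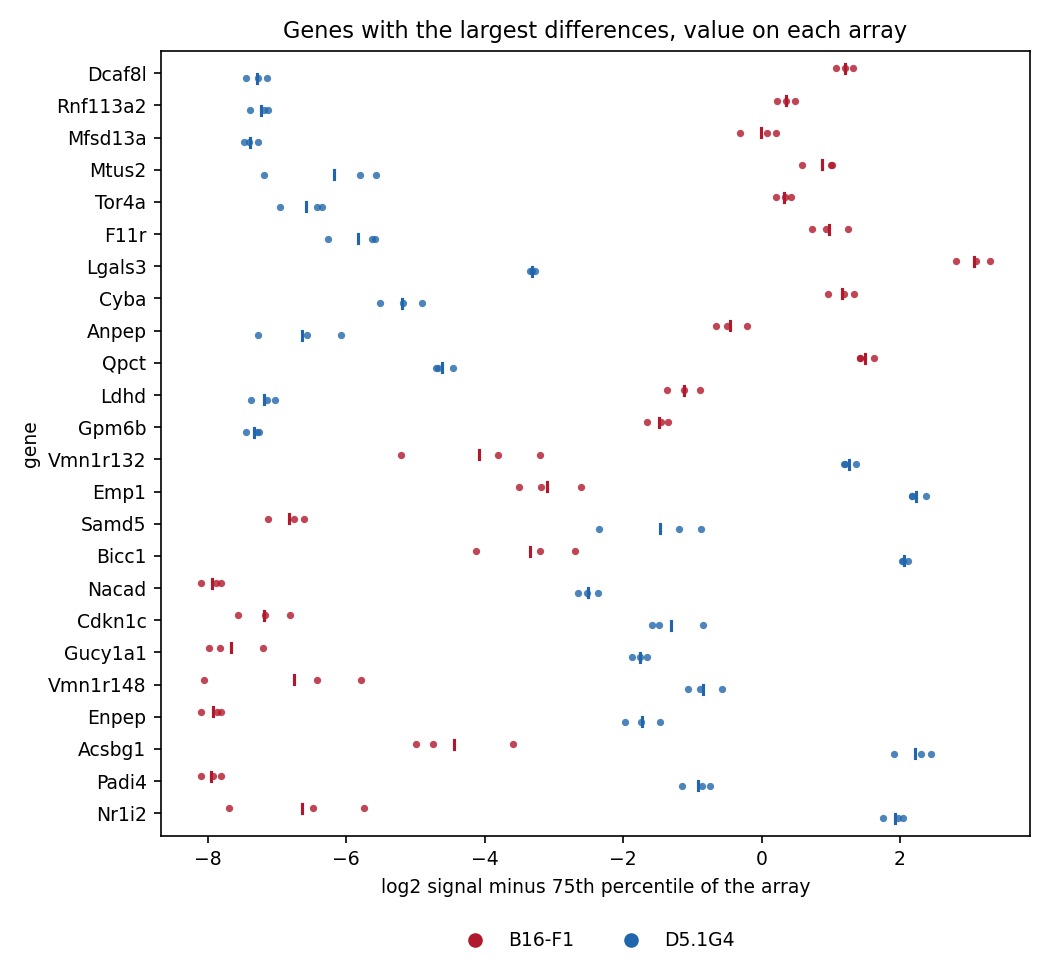
Log2 signal minus the array's 75th percentile (horizontal axis) on each of the 3 B16-F1 arrays (red points) and 3 D5.1G4 arrays (blue points) for the 12 genes with the largest positive and the 12 with the largest negative difference (vertical axis), with the mean of each line as a short bar. The lines do not overlap for any of these genes, which the rule that chose them required, and the differences of Acsbg1 and Lgals3 are -6.66 and 6.38 log2 units.

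Of the genes set in advance whatever their values, Tgfb1, the gene of the cytokine transforming growth factor beta 1, and Foxc2, a forkhead transcription factor, rose. Tgfb1 was at least 6.30-fold higher in B16-F1 (adjusted p = 2.23e-05) and Foxc2 at least 4.39-fold (adjusted p = 0.000401), and neither was well above background in D5.1G4. Vegfa, the vascular endothelial growth factor A gene, was 1.69-fold higher (0.76, SE 0.11, adjusted p = 0.00358), under the minimum fold, and another of its probes gave -0.60. Ccl2 was above background on 2 D5.1G4 arrays and 0 B16-F1 arrays and was not tested, and Cdkn2a, the gene of the cell cycle inhibitor p16, was not above background on any array. Actb differed by -0.41 (adjusted p = 0.0409) and Gapdh by -0.57 (adjusted p = 0.0901), and neither reached the minimum fold.

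Gene lists fixed in advance gave 521 tested members, of which 156 (29.9%) were called. Of 31 lists tested as a whole, 2 were shifted, MAPK pathway output and interferon-stimulated genes, both upward in B16-F1, and 4 had an unadjusted p of 0.05 or less. With an estimated correlation 0 of the 31 passed. Fry, which does not compare a list with other genes, gave 21 lists moving on balance 1 way and 31 changing in either direction. The number of members called, adjusted over the list alone, equalled that over all genes in every list except immune suppression (4 higher in place of 3) and Wnt signalling (5 lower in place of 4).

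Genes that report the output of the MAPK pathway, through which growth factor receptors and RAF kinases act, were higher as a group in B16-F1. Of 19 tested members 8 rose and 2 fell, with a median log2 difference of 0.84 (0.66 with bounds in place of values for genes not above background in a line). Etv5, an ETS transcription factor induced by the pathway, rose (log2 difference 4.32, SE 0.20, adjusted p = 5.69e-05). The feedback inhibitors Spry1 and Dusp6 rose by 1.92 (SE 0.28) and 1.85 (SE 0.15), and Spry4 was at least 1.24-fold higher, on 2 measured D5.1G4 arrays, a call that was lost when outlier spots were kept (adjusted p = 0.105), with the authors' values (0.134) and with normexp (0.462). Etv4, Fos, Ier3 and Etv1 rose too, by 1.73, 1.63, 1.08 and 1.03, while the ephrin receptor genes Epha4 and Epha2 fell by 1.39 and 1.20, the latter with an adjusted p of 0.052 with slide as a block. Camera gave p = 0.000602 and an adjusted p of 0.0186 for the list (adjusted p = 0.973 with an estimated correlation). The median within slide 2, where B16-F1 replicate 1 alone stands for its line, was 1.08. Over the upper part of the features by mean signal the call was lost (adjusted p = 0.0817).

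**Figure D3:**
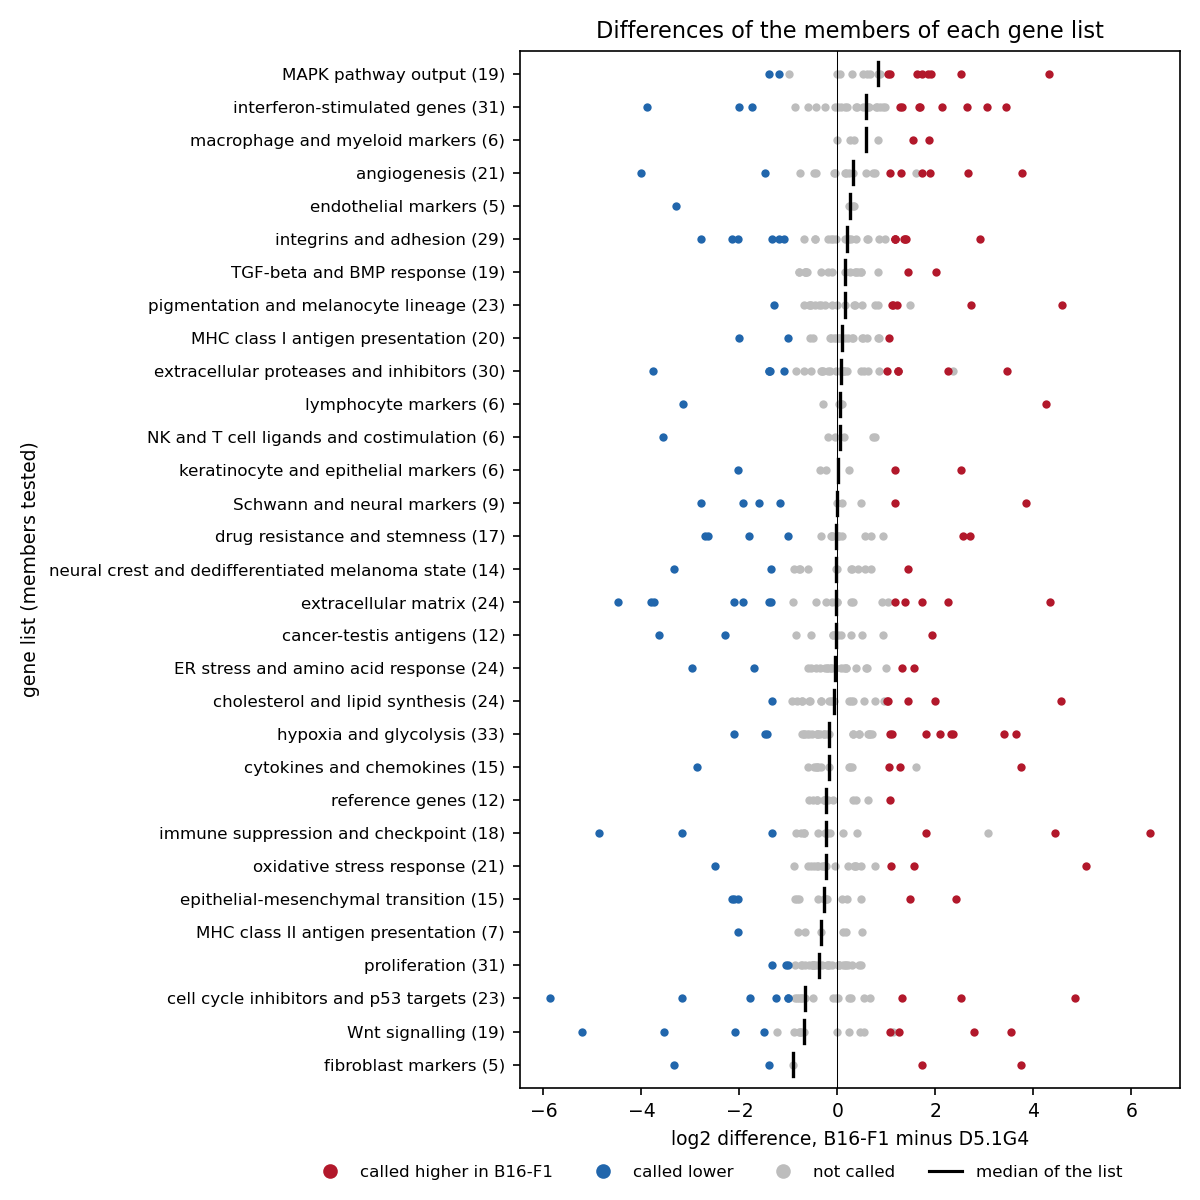
Log2 difference between B16-F1 and D5.1G4 (horizontal axis) of every tested member of the 31 lists tested (vertical axis, number of members in brackets), with members called higher in red, called lower in blue and not called in grey, and the median of each list as a black bar. MAPK pathway output has the highest median, 0.84, interferon-stimulated genes have a median of 0.60, and most lists hold members called in both directions.

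Interferon-stimulated genes, which serve antiviral defence and antigen display, were also higher as a group, though not uniformly. Of 31 tested members 8 rose and 3 fell, with a median of 0.60 (0.51 with bounds). Trim30a was at least 2.47-fold and Oas2 at least 1.02-fold higher, the 2',5'-oligoadenylate synthetase gene Oas1a rose by 3.05 (SE 0.37) and Usp18, which removes ISG15 from proteins, by 2.64 (SE 0.38, above background on 1 of 3 D5.1G4 arrays). Bst2, Irf9, Gbp3 and Parp14 rose by 1.70, 1.66, 1.32 and 1.28. Oasl1 fell (adjusted p = 0.000187) and was above background on 1 of 3 B16-F1 arrays, and Ifih1, a sensor of viral RNA, and Ifit1 fell by 2.02 and 1.73. Camera gave p = 0.00186 and an adjusted p of 0.0289 (adjusted p = 0.973 with an estimated correlation). The median within slide 2, where B16-F1 replicate 1 alone stands for its line, was 0.81. The camera call was lost without B16-F1 replicate 1 (adjusted p = 0.264), without D5.1G4 replicate 1 (0.0999), with quantile normalization (0.141) and over the upper part of the features by mean signal (0.35). Fry gave an adjusted p of 0.0614 for this list.

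The core of the melanocyte programme was expressed in both lines. Of 23 tested pigmentation and melanocyte lineage genes 5 rose, 1 fell and 17 were not called (camera adjusted p = 0.541). Kit, the receptor for stem cell factor, was at least 5.06-fold higher in B16-F1 and not well above background in D5.1G4 (adjusted p = 3.83e-05). Trpm1, a cation channel of melanocytes, rose by 2.73 (SE 0.30), though 2 further probes gave -0.60 and 1.05, and the transporter genes Slc45a2 and Slc24a5 and the melanocortin receptor gene Mc1r rose by 1.22, 1.13 and 1.11. Pax3, a transcription factor of the neural crest, fell by 1.30 (SE 0.12), where another probe gave -0.78. Mitf, Sox10 and Tyr differed by 0.37, 0.15 and 0.78, and Mlana, Dct and Tyrp1 by -0.68, -0.54 and -0.45, none of them called. In the neural crest and dedifferentiated state list (14 tested, adjusted p = 0.94) Ccn2 rose by 1.45 and Pdgfrb, a receptor for platelet-derived growth factor, and Tcf4 fell by 3.33 and 1.36. In the epithelial-mesenchymal transition list (15 tested, adjusted p = 0.797) the transcription factor genes Foxc2 and Zeb1 rose (Zeb1 at least 2.08-fold), whereas N-cadherin (Cdh2) fell by 2.15 (SE 0.19), E-cadherin (Cdh1) was at least 2.19-fold lower, a call lost with the authors' values (adjusted p = 0.09) and with normexp (-0.30, adjusted p = 0.814), and fibronectin (Fn1) was called lower on only 1 measured D5.1G4 array (-2.10), a call lost without the arrays of slide 1 (adjusted p = 0.0677).

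Most antigen presentation genes were not called, which also held over all features tested, where 15.2% were called (29.9% over the list members). Among 20 tested MHC class I genes (camera adjusted p = 0.917) the peptide-trimming enzyme gene Erap1 rose by 1.06 and Nlrc5, a transactivator of class I genes, and the peptide transporter gene Tap2 fell by 2.02 and 1.01, where another Nlrc5 probe gave 0.19 and the Nlrc5 call was lost with the mean over its probes (adjusted p = 0.125) and with normexp (0.156). Erap1 fell short of the minimum fold without B16-F1 replicate 2 (0.96) or D5.1G4 replicate 2 (0.98), and Tap2 lost its call without B16-F1 replicate 3 (-0.84), without D5.1G4 replicate 3 (-0.86) and with slide as a block (adjusted p = 0.0857). Of 7 MHC class II genes (0.917) H2-DMb1 fell by 2.03 (SE 0.19), and of 6 ligands of NK and T cells (0.94) the adhesion ligand gene Icam2 fell by 3.55 (SE 0.24).

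Secreted immune factors moved in both directions. Of 15 tested cytokines and chemokines (camera adjusted p = 0.917) Cx3cl1, the chemokine fractalkine, rose 13.5-fold (log2 difference 3.76, SE 0.15, adjusted p = 4.11e-05), and Il18 and Cxcl10 rose by 1.28 and 1.06. Ccl5, a chemokine that attracts T cells, fell by 2.86 (SE 0.30). The Cxcl10 call was lost without B16-F1 replicate 1 or 2 (adjusted p = 0.0577 and 0.0762) or D5.1G4 replicate 2 or 3 (0.0937 and 0.0995). Of 18 immune suppression and checkpoint genes (0.917) Lgals3, Tgfb1 and Lgals9 (1.82) rose, and the growth differentiation factor gene Gdf15, at least 20.6-fold lower, the death receptor gene Fas (-3.18, SE 0.31) and Tgfb3 (-1.33) fell. The median of the cytokine list was -0.18 while its mean was 0.19 and camera gave an upward direction, and the median of the suppression list was -0.23 with a mean of 0.15 and a downward direction in camera.

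Angiogenesis genes included 6 that rose and 2 that fell of 21 tested. Camera gave an unadjusted p of 0.0274 and an adjusted p of 0.212 for the list, which passed with only features well above background on all 6 arrays (adjusted p = 0.0416). Angpt2, a vessel-destabilising ligand, rose by 3.77 (SE 0.33, adjusted p = 0.000536). The inhibitors of vessel growth Serpinf1, Thbs1 and Thbs2 rose as well, Serpinf1 by 2.67 (SE 0.26), Thbs1 by 1.89 (SE 0.14) and Thbs2 at least 1.30-fold, with the semaphorin co-receptor gene Nrp1 (1.30). Col18a1, the source of endostatin, was at least 3.35-fold lower and Nrp2 fell by 1.47.

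The extracellular matrix list held 5 members that rose and 7 that fell of 24 (camera adjusted p = 0.917), and partner chains of the same collagens moved apart. Col4a1 rose by 2.27 (SE 0.20) and Col4a2 fell by 3.81 (SE 0.33), and Col1a1 rose by 1.73 (SE 0.15) and Col1a2 fell by 3.74 (SE 0.13). These differences were each larger than the spread between replicates, while the difference between the chains was not tested. For Col4a2, Col1a1 and Col1a2 no other probe was tested, so an effect of the single probe cannot be told from one of the gene. The laminin gene Lamb1 rose 20.3-fold (4.35, SE 0.23) and the elastic fibre gene Emilin1 fell (-4.47, SE 0.21, adjusted p = 6e-05) and was above background on 1 of 3 B16-F1 arrays. Of 30 proteases and inhibitors (0.917) 5 rose and 5 fell, among them the collagen-cleaving cathepsin gene Ctsk, at least 4.98-fold higher, heparanase (Hpse, 2.26, SE 0.41), Adamts9, at least 4.71-fold lower, and Adam19 (-1.39), while Reck, an inhibitor of matrix metalloproteinases, fell by 1.38. Of 29 integrin and adhesion genes (0.797) 7 rose, among them Ncam1 (2.92, SE 0.14) and the cadherin gene Cdh13 (1.18, above background on 2 of 3 D5.1G4 arrays), and 6 fell, among them Jam2 (-2.79, SE 0.24), Cdh2 and Cdh1. Other probes gave smaller differences for Hpse (1.03), Ncam1 (1.08 and 2.04) and Jam2 (-1.27).

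Proliferation genes showed 0 called higher and 3 lower of 31, with a median of -0.37. Camera gave an unadjusted p of 0.0113 and an adjusted p of 0.116 for the list. Cyclin E1 (Ccne1) fell by 1.33 (SE 0.13), a call lost with the mean over its probes (-0.84), and Cenpe and the proliferation marker gene Mki67 fell by 1.04 and 1.02. Cenpe and Mki67 fell short of a 2-fold difference without B16-F1 replicate 3 (-0.94 and -0.95), without D5.1G4 replicate 2 (-0.99 and -0.94) and within slide 2 (-0.84 and -0.94). The list passed without B16-F1 replicate 1 (adjusted p = 0.0392) and with normexp (0.00362). Of 23 cell cycle inhibitors and p53 targets (0.362, median -0.67) 3 rose and 6 fell. The death receptor gene Tnfrsf10b rose 29.0-fold (4.86, SE 0.45, adjusted p = 0.000686) and Perp, a desmosomal p53 target, by 2.53 (SE 0.12). Sesn2 rose by 1.32, a call lost with slide as a block (adjusted p = 0.0603) and without B16-F1 replicate 2 or 3 (0.114 and 0.12) or D5.1G4 replicate 2 or 3 (0.111 and 0.124). Cdkn1c and Fas fell, as did Gadd45b, by 1.78 (SE 0.16).

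Wnt signalling genes moved in both directions, 4 higher and 4 lower of 19 (camera adjusted p = 0.917, median -0.69). Tcf7, a transcription factor of the pathway that was above background on 1 of 3 D5.1G4 arrays, and Dkk3, a secreted protein of the Dickkopf family, rose by 3.54 (SE 0.28) and 2.79 (SE 0.15). Nkd1, a feedback inhibitor, fell (adjusted p = 3.58e-05), with no fold given because its probe was not well above background on any B16-F1 array while another of its probes was, and the ligand gene Wnt10a fell (adjusted p = 0.00202) and was above background on 1 of 3 B16-F1 arrays. Of 19 TGF-beta and BMP response genes (0.917) 2 rose and 0 fell, Id3, an inhibitor of DNA binding, by 2.02 (SE 0.15) and Ccn2, while the ligand gene Tgfb1 stands in the immune suppression list.

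Metabolic genes included large single differences without a shift of the lists. Of 33 hypoxia and glycolysis genes (camera adjusted p = 0.917) 8 rose and 3 fell. The lactate exporter gene Slc16a3 rose 12.6-fold (log2 difference 3.66, SE 0.18), the aldolase gene Aldoc 10.6-fold (3.40, SE 0.11) and the carbonic anhydrase gene Car9 by 2.37 (SE 0.19), and Pdk1, which restrains pyruvate entry into mitochondria, rose by 2.33 (SE 0.41), a call lost with slide as a block (adjusted p = 0.0585). Eno2, Pfkp and Ldhb fell by 2.10, 1.48 and 1.44. Of 24 cholesterol and lipid synthesis genes (0.917) 5 rose and 1 fell. Scd1, which desaturates fatty acids, rose 23.8-fold (4.57, SE 0.12, adjusted p = 1.65e-05), Srebf1, a transcription factor of lipid synthesis, by 2.00 (SE 0.16) and Fdft1 by 1.45 (SE 0.20, but 0.65 and no call with the mean over its probes), and Stard4 fell by 1.34. The hypoxia list had a median of -0.18 and a mean of 0.32, and the lipid list a median of -0.08 and a mean of 0.27, with an upward direction in camera for both.

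Stress and drug response genes were mostly not called, as held over all features tested, where 15.2% were called. Of 21 oxidative stress genes (camera adjusted p = 0.955, median -0.24, mean 0.16, upward in camera) 3 rose and 1 fell. The quinone reductase gene Nqo1 was at least 7.47-fold higher in B16-F1 and not well above background in D5.1G4 (adjusted p = 3.83e-05). The cystine transporter gene Slc7a11 and the haem oxygenase gene Hmox1 rose 2.97-fold and 2.14-fold, and the extracellular superoxide dismutase gene Sod3 fell by 2.50 (SE 0.19). Of 24 ER stress and amino acid response genes (0.976) 2 rose, Slc7a11 and Sesn2, and 2 fell, Fgf21 by at least 2.74-fold (but -0.45, adjusted p = 0.733, with normexp) and the stress-induced transcription factor gene Atf3 by 1.71 (SE 0.18, 2 D5.1G4 arrays measured). Of 17 drug resistance and stemness genes (0.976, median -0.02, mean -0.08, upward in camera) Prom1, the gene of the surface protein CD133, was at least 1.41-fold and Aldh1a3 at least 3.82-fold higher, and 4 fell, among them the aldehyde dehydrogenase genes Aldh1a1 (-2.65, SE 0.37) and Aldh1a7, at least 2.36-fold lower (but -0.36, adjusted p = 0.791, with normexp).

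Of 12 tested cancer-testis genes (camera adjusted p = 0.94) 1 rose and 2 fell. Rhox5 and Xlr4b, both X-linked, were at least 5.31-fold and 4.23-fold lower in B16-F1 and not well above background there. Ddx4, a germ cell helicase gene, was at least 1.51-fold higher, a call lost with slide as a block (adjusted p = 0.105) and without D5.1G4 replicate 2 or 3 (0.0553 and 0.0586). Of the 9 genes of the Y-linked and X-inactivation list, Xist included, 0 were above background on any array, and the list was not tested.

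Markers of other cell types gave no list past the test, with 5 to 9 members tested in each. Macrophage and myeloid markers had 2 of 6 called higher, Fcer1g (1.86, SE 0.14) and Cd14 (at least 1.35-fold), with an adjusted p of 0.311 for the list and a median of 0.59 (0.39 with bounds) that was 0.02 within slide 2. The Cd14 call was lost without B16-F1 replicate 1, 2 or 3 (adjusted p = 0.0595, 0.0881 and 0.0577). Among 6 lymphocyte markers (0.94) the kinase gene Lck, above background on 1 of 3 D5.1G4 arrays, rose by 4.26 (SE 0.16) and Cd4 fell by 3.15 (SE 0.28). Of 9 Schwann and neural markers (0.917) 2 rose and 4 fell, with the myelin gene Pmp22 at -2.78 (SE 0.16, 2 D5.1G4 arrays measured) and S100b and Tubb3 at -1.93 and -1.59. Of 5 fibroblast markers (0.94) Pi16, at least 2.90-fold higher, and Col1a1 rose and Pdgfrb and Postn (-1.39) fell. Of 6 keratinocyte and epithelial markers (0.917) Perp and Sfn (1.18) rose and Cdh1 fell, the last not with the authors' values (adjusted p = 0.09) or normexp (0.814), and of 5 endothelial markers (0.976) Robo4 was at least 6.51-fold lower. The endothelial list had a median of 0.26 and a mean of -0.43, and its median was -0.31 within slide 2, as those of lymphocyte (0.06) and keratinocyte markers (0.01) were -0.34 and -0.32. In the NK and T cell ligand list the median was 0.05 and the mean -0.36.

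The arrays of slide 1 stood apart in probes for olfactory and vomeronasal receptors and defensins. Without them 1 B16-F1 array is left to compare the 118 named genes. Named genes that then lost their call were Tcf4, Fn1, Tap2, Cxcl10, Hpse, Cenpe, Mki67, Spry1, Pdk1, Sesn2, Stard4, Ddx4, Postn, Cd14, Sfn and Ywhaz. Among these, the differences of Hpse (2.42), Pdk1 (2.34) and Tcf4 (-1.29) stayed close to those over all arrays. Those of Sesn2 (0.534), Tap2 (-0.696), Cenpe, Mki67, Sfn and Ywhaz fell short of the minimum fold, while that of Cxcl10 grew. Whether these calls were lost through fewer arrays or through the slide was not tested. Normexp ended the calls of 39 named genes, with adjusted p-values from 0.0512 to 0.814, for a cause that was not tested. These were Enpep, Gucy1a1, Cdkn1c, Nacad, Samd5, Pdgfrb, Foxc2, Cdh1, Nlrc5, Erap1, Tap2, Oasl1, Trim30a, Usp18, Cxcl10, Gdf15, Fas, Col18a1, Adamts9, Ctsk, Jam2, Spry4, Nkd1, Wnt10a, Fgf21, Sesn2, Prom1, Aldh1a7, Aldh1a1, Aldh1a3, Rhox5, Xlr4b, Ddx4, Pi16, Postn, Cd14, Robo4, Sfn and Ywhaz. Of 1159 olfactory receptor probes, 25.8% and 22.8% were well above background on B16-F1 replicates 2 and 3, the arrays of slide 1, against 11.1% on B16-F1 replicate 1 and 11.9%, 10.9% and 10.2% on the D5.1G4 arrays. Of 290 vomeronasal receptor probes these shares were 31.1% and 27.7% on slide 1 against 15.5% on B16-F1 replicate 1 and 19%, 15.2% and 14.9% on D5.1G4 replicates 1, 2 and 3. Of 70 defensin probes they were 27.1% and 15.7% on slide 1 against 4.3% to 8.7% on the other arrays. Of 12 reference genes (camera adjusted p = 0.94) only Ywhaz was called (1.08, SE 0.27), and its call was lost with slide as a block (adjusted p = 0.161), without B16-F1 replicate 3 (0.80) and without D5.1G4 replicate 2 or 3 (adjusted p = 0.0725 and 0.0865).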

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

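Slide as a random block, the arrays of slide 2 alone, slide 1 left out and the brighter part of the features by mean signal were tests chosen after the result was seen. Against 2799 called features (1159 higher, 1640 lower), normexp gave 1274 (553 and 721), of which 1217 were shared, the brighter part of the features 838 (308 and 530), adjusted p without a minimum fold 6434 (2671 and 3763) and limma's treat against a 2-fold difference 888 (361 and 527). The last 3 follow from their construction, with fewer features tested or another threshold, and for normexp the cause was not tested. The spread between B16-F1 replicates rose from 0.208 to 0.343 with normexp. The other settings gave 2057 to 3478 features, and leaving out an array 2530 to 3375, the highest without B16-F1 replicate 1 (50.8% higher in place of 41.4%). Median scaling shifted the median of all features to -0.129 and gave 1119 higher and 2136 lower. No called feature was called in the opposite direction, except 6 features where every probe was tested by itself. Leaving out saturated features removed 0 and tested nothing.

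Of the gene lists, 2 were past the threshold, against 3 with normexp, 3 with only features well above background on all 6 arrays, 1 with quantile normalization, 0 in the brighter part of the features, 0 with an estimated correlation and 21 with fry, which asks another question. Leaving out an array gave 1 to 2, and 1 without D5.1G4 replicate 1. The 2 lists without B16-F1 replicate 1 were MAPK pathway output and proliferation (camera adjusted p = 0.0392 for each). Interferon-stimulated genes were lost there (0.264). The cause was not tested. Of 2579 results of the 118 named genes under alternatives, 2458 kept their direction and side of the threshold, 121 lost the call and 0 reversed. Of the 115 called genes, 106 kept their call in every fit without 1 array that could test them. Fn1, measured on 1 D5.1G4 array, could not be tested without D5.1G4 replicate 1. In all alternatives that tested them 65 kept their call. Not every alternative tested every named gene: the stricter filter on dim probes held 69 and the brighter part of the features 35. Normexp took 39 of the lost calls. Same-numbered arrays of the lines deviated with correlations of -0.381, -0.026 and -0.302 across features. Same-numbered arrays lay on different slides, so these values cannot decide whether the replicate numbers pair the arrays. A replicate block gave 2583 called features and 2 lists. Signal over background limits the folds of 466 called features that were not well above background in 1 line, which are bounds.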

Other observations

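The tests of gene families, of the slide for each pattern, of dim probes and copies for chromosome 4 and of the vomeronasal receptor genes were chosen after the result was seen, as was the wider set of genes in the test for mixed RNA.

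Clustered protocadherins of the beta group, cell surface proteins that mediate contacts between neurons, were called higher in B16-F1 more often than other genes. Among 211 families of genes that share a name stem and had at least 8 tested members, with 422 tests, the Pcdhb family had 7 of 14 members called higher and 0 lower (Fisher's exact test, adjusted p = 0.00769). Pcdhb16 and Pcdhb17 rose by 1.37 and 1.31, and Pcdhb14, Pcdhb15 and Pcdhb11, not well above background in D5.1G4, were at least 2.77-fold, 2.24-fold and 1.49-fold higher. The count was 7 whichever array was left out, while quantile normalization gave 5, median scaling 6, normexp 1 and slide as a block 8, with a positive median of fitted values each time. With slide 1 left out, 1 B16-F1 array remained and the median was 1.08. The family rests on dim probes: 5 members were well above background on all 6 arrays, 2 of them called higher. In the upper part of the features by mean signal 0 members were tested. The Fisher test counts the members as independent, which was not checked.

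Collagen genes and genes of the Cfap name stem were called lower more often than other genes. Of 23 collagen genes 9 fell and 3 rose (Fisher's exact test for lower, adjusted p = 0.00769), a family that overlaps the extracellular matrix list, with Col9a1 at -4.09 and Col2a1 and Col17a1, not well above background in B16-F1, at least 9.06-fold and 3.83-fold lower. Of 13 Cfap genes, named for cilia and flagella, 6 fell and 0 rose (adjusted p = 0.0296), with Cfap70 and Cfap69 at -3.71 and -2.72 and Cfap52 at least 1.93-fold lower. Normexp called 4 collagen and 2 Cfap genes lower, and 4 to 6 Cfap genes were called lower when an array was left out, with 1 called higher without B16-F1 replicate 1. Both family medians were negative under every scaling tried. Olfactory receptor genes, 153 tested, had 1 called higher and 1 lower, fewer than other genes (adjusted p = 0.0234 and 0.00769). Their median of 0.30 turned to -0.30 within slide 2, and without B16-F1 replicate 1 there were 24 called higher.

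B16-F1 replicate 1 lay at least 2-fold below the mean of replicates 2 and 3 in 1824 features and above it in 94, and over 5 equal classes of mean signal 31.6% of the dimmest features but 0.1% of the brightest were lower. Mixing with D5.1G4 RNA is argued against, since over 2 genes bright in D5.1G4 and not above background on replicates 2 and 3 the median excess of this array over those replicates was 0.23% of the D5.1G4 signal, and over 218 such genes of any level in D5.1G4 it was 0.9%, where a drop by 2-fold needs 50%. The slide is a candidate explanation: over the same features the D5.1G4 arrays of slide 2 lay below the D5.1G4 array of slide 3, with a median of -0.58 against 0.05 over all features. No biological explanation was tested.

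Genes of chromosome 4 were lower in B16-F1 as a group. The median of 870 genes was -0.43 relative to other genes, 166 fell and 35 rose. A permutation test that rotated the differences along the genome 10000 times gave p = 4e-04, adjusted p = 0.008 over 20 chromosomes. The slide, the normalization and dim probes are argued against as the whole cause, since the difference was -0.39 within slide 2, -0.42 or further from 0 with quantile normalization and normexp, and -0.49 in the brighter part of the features. Fewer copies of the chromosome in B16-F1 than in D5.1G4 may account for it, as a hypothesis, because each of 4 parts in gene order was lower, the nearest to 0 by -0.39. The values compare the lines and cannot tell in which of them the chromosome changed. Chromosome 18 came next, at -0.31, but did not pass the rotation test (adjusted p = 0.541). DNA was not analysed here, and other differences between the lines stay open.

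Among 23 tested vomeronasal receptor genes of the Vmn1r family on chromosome 7, a group noticed in the data and not tested as such, 11 were called lower in B16-F1, with a median of -3.50 among these, and 12 were not called. The whole Vmn family, 53 tested with 11 lower and 0 higher, did not pass the test of families (adjusted p = 0.236). Within slide 2 the called gene nearest to 0 differed by -1.94, so for the called genes the lines also differed within that slide. These genes were picked by calls that used the same arrays, so this is not an independent test of the slide. The measure was set after the median over all 23 genes, -0.98, had fallen between the bounds first set. For the 23 genes as a group the slide stays undecided. Lower expression of the whole stretch stays open, as the 3 genes inside it that were not called, Nlrp4e (0.45, SE 0.55), Vmn1r168 (0.46, SE 0.41) and Vmn1r173 (0.37, SE 0.40), are few and differed by -0.55, 0.13 and -0.23 within slide 2. A transcript read by probes of several near-identical genes could give the same picture and stays open, as probe sequences were not used here. The 12 genes not called do not speak against it, since all were dimmer in D5.1G4 than the called genes. Their D5.1G4 means ran from -6.41 to -3.17, against -3.15 or more for the called genes, whose median was -0.75. Genes not called thus had less room to fall, also inside the stretch, where Nlrp4e had a D5.1G4 mean of -4.60.

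The 6 arrays can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split called 2799 features, as many as in 1 of the 10 splits, itself, and the highest of the other splits called 1, as did the split that follows the slide. Every other split puts arrays of both lines on each side, so the difference between the lines adds to its spread. Their low counts therefore cannot show whether the slide has an effect.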
